A study of Homo sapiens with 4 samples.

How the data were processed

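RNA abundance was measured by mRNA sequencing in 4 libraries of Jurkat cells, an established human line of T-cell acute lymphoblastic leukaemia. Of these, 2 libraries came from cells with a control short hairpin RNA (shcontrol) and 2 from cells with a short hairpin RNA against BDH1 (shBDH1). Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase and made into mRNA libraries that were read as paired ends. The submitters' processing notes name the human genome build hg38, FastQC 0.11.9 and HISAT2 2.2.1. The read counter, the annotation release, the strand setting and the tool that set the size factors are not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

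The deposited table holds 1 value per gene and library for 25122 genes, and its values are a normalized signal: gene read counts that the authors had divided by 1 size factor per library. This was found from the values, since all values of a library were whole multiples of 1 step, although the table's own name calls the counts raw. Dividing by the step gave whole reads for 100.0% of the values of each library, within a tolerance of 0.01 reads. The size factors recovered were 0.9739 and 0.9785 for shcontrol and 1.0174 and 0.9944 for shBDH1. The recovered reads summed to 28681511 and 28797402 for shcontrol and to 29453383 and 28777374 for shBDH1, so depth hardly differed between groups. In the table, 21 gene symbols had turned into dates; each was renamed from its gene ID. Of the 25122 gene IDs, 25010 had a position in GENCODE 29, whose assembly GRCh38 is the build called hg38. No column of per-library values was left unused.

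The test planned before the data were examined was edgeR's quasi-likelihood test on raw counts. Because the deposited values were already normalized, the main test became limma on log2(value + 1), with an intensity-dependent prior on the variance, and edgeR, DESeq2 and limma-voom were run on the recovered reads as alternatives. That change was made after the values of BDH1, MYC and CDK4 had been seen and before any test was run. Genes with a mean value of at least 10 over the 4 libraries entered, which left 19301. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and are given as shBDH1 relative to shcontrol with their standard error (SE). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The residual degrees of freedom were 2 and the prior ones 25.8. The median SE was 0.12 over all genes, 0.064 at a mean of 1000 or more and 0.50 at a mean under 100.

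Gene lists for a T-cell leukaemia line, 39 in all, were written before the data were examined; 779 of their 855 entries were found in the table. Lists with at least 5 measured members, 36 in all, were tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation, camera rests on the 2 residual degrees of freedom and has little power, so a missing call there does not decide against a list. The genes named in the report follow a rule fixed at the same time: BDH1, MYC and CDK4 whatever their values, then the 12 largest rises and the 12 largest falls among protein-coding genes that passed the test, averaged at least 5 CPM (reads scaled to equal library totals) in the higher group and had groups that did not overlap and an established gene name, and then up to 4 members with the smallest p of each list. Some genes that the rule takes are not reported here. A gene named outside that rule is said to be.

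Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The fits were tested on reads simulated for this comparison with 50 genes changed at each fold size. Among 19323 genes tested, limma found 17 of the 50 changed 1.25-fold, 29 of those changed 1.5-fold, 34 of those changed 2-fold and 46 of those changed 4-fold, with 10 calls among unchanged genes. Far fewer genes were changed in the simulation than the 41.1% called in the data, where the adjusted threshold is therefore laxer. These rates do not measure the sensitivity in the data. Settings tried as alternatives were other scalings, filters, pseudocounts and tests, the replicate number as a block, and each library left out in turn.

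The libraries of a group were compared before they were averaged. The chi-square per degree of freedom over genes was 3.72 between the shcontrol libraries and 5.13 between the shBDH1 libraries, so neither pair was 1 library deposited under 2 names, against 46.2 to 49.2 between groups. No strand setting is known, so genes that overlap on opposite strands may share reads. Genes with near-identical copies, such as ribosomal protein genes with their pseudogenes, histone genes and HSPA1B with HSPA1A, are likewise uncertain.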

Results

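The data are normalized read counts per gene from mRNA sequencing of 4 Jurkat libraries, 2 with a control hairpin (shcontrol) and 2 with a hairpin against BDH1 (shBDH1). BDH1 encodes the mitochondrial 3-hydroxybutyrate dehydrogenase, which interconverts the ketone bodies acetoacetate and 3-hydroxybutyrate. The libraries held 28681511 and 28797402 (shcontrol) and 29453383 and 28777374 (shBDH1) reads in genes. The study's description asks about MYC as a gene downstream of BDH1. It also speaks of cells in which MYC was restored; such cells were not analysed here, and the single comparison below is shBDH1 against shcontrol.

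BDH1 mRNA fell in the shBDH1 libraries, but modestly: 1316 ± 135 normalized counts (SD, n = 2) remained against 1818 ± 132 (SD, n = 2) in shcontrol, 27.6% less. The 4 library values were 1725 and 1911 in shcontrol and 1221 and 1412 in shBDH1. The log2 fold change was -0.47 (SE 0.08, 95% interval -0.63 to -0.31, limma adjusted p = 1.5e-05). Of the 4020 genes that fell, 1515 fell by more than BDH1 did. BDH1 (ENSG00000161267) lies on chromosome 3 from 197509783 to 197573323 (hg38).

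MYC, the transcription factor that drives growth and ribosome production, fell from 14744 ± 85.6 to 7411 ± 60.0 normalized counts (SD, n = 2 each), a log2 fold change of -0.99 (SE 0.04, limma adjusted p = 2.7e-18). CDK4, the cyclin D-dependent kinase named in the study's title, fell from 5945 ± 85.5 to 4030 ± 171 (SD, n = 2 each), a log2 fold change of -0.56 (SE 0.05, limma adjusted p = 1.3e-10). TSPAN31 overlaps CDK4 by 2485 bases on the opposite strand and had the same log2 fold change of -0.56 (named after its values were seen), so reads of this pair may be shared. The 3' UTR of BDH1, and not those of MYC and CDK4, holds the heptamer CCCGAGA, whose carriers lay lower in shBDH1 as a set. These genes lie on chromosome 8 from 127735434 to 127741434 (MYC, ENSG00000136997) and chromosome 12 from 57747727 to 57756013 (CDK4, ENSG00000135446).

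**Figure D1:**
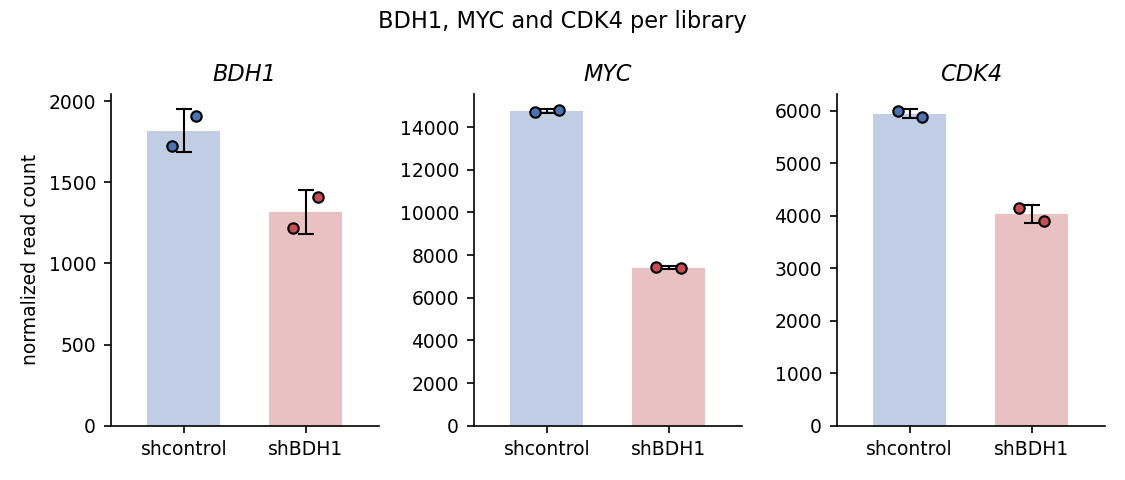
Normalized read counts of BDH1, MYC and CDK4 (vertical axes, starting at 0) in shcontrol and shBDH1; bars show means, error bars the SD and points the 2 libraries of each group. Both shBDH1 libraries lie below both shcontrol libraries for each gene, with BDH1 at 72.4% and MYC at 50.3% of the shcontrol mean.

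The change reached well beyond these genes. Of 19301 genes tested, 3910 rose and 4020 fell (limma, adjusted p under 0.05), together 41.1%. Among genes that changed at least 2-fold, 909 rose and 312 fell; these were 564 and 139 at a mean under 100, 281 and 93 at a mean of 100 to 1000, and 64 and 80 at a mean of 1000 or more. Which direction held more genes depended on the scaling: edgeR called 4447 higher and 3267 lower with upper-quartile factors, and 4215 higher and 3598 lower with library totals only. The groups did not overlap for 69.0% of the genes tested, where chance gives 33.3%. The first principal component held 65.9% of the variance and separated the groups.

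The 12 largest rises were LGALS1, CD93, APOBR, FAM131B, HDC, MYO1F, KCNIP1, KRT72, PRF1, KCNMB1, ETV5 and PAK3, with log2 fold changes from 4.24 for LGALS1 down to 3.03 for PAK3. LGALS1, the secreted lectin galectin-1, rose from 12.8 ± 6.56 to 245 ± 2.36 normalized counts (SD, n = 2 each). ETV5, an ETS factor induced by ERK signalling, rose from 74.8 ± 11.3 to 668 ± 30.7, and HDC, which makes histamine, rose from 26.1 ± 8.05 to 355 ± 86.6. PRF1, the pore-forming protein of cytotoxic cells, rose from 18.4 ± 2.84 to 174 ± 16.2. KCNIP1 and KCNMB1 overlap on opposite strands by 15007 bases and had near-equal counts, 404 and 373 in shBDH1, so they may be 1 signal. All 12 had shcontrol means between 10.2 and 74.8.

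The largest falls included PRX, OPALIN, DNTT, EMC10, STC2, C11orf74, CHAC1, FAM71E1, MRPL37, KANK4 and SLC7A5, with log2 fold changes from -2.63 for PRX to -1.68 for SLC7A5. DNTT, the terminal transferase of immature lymphocytes, fell from 6055 ± 78.6 to 1361 ± 22.0 normalized counts (SD, n = 2 each). SLC7A5, the large neutral amino acid transporter, fell from 33867 ± 1128 to 10588 ± 247, the secreted glycoprotein STC2 from 4887 ± 18.2 to 1195 ± 25.7, and CHAC1, which degrades glutathione, from 1835 ± 44.7 to 529 ± 28.0. C11orf74 overlaps RAG2, and EMC10 overlaps FAM71E1, on opposite strands. Opposite-strand transcripts, named after their values were seen, also overlap DNTT (AL136181.1, 2300 bases, log2 fold change -1.99), EMC10 (AC020909.3, 3233 bases, -2.29) and SLC7A5 (AC126696.2, 1132 bases, -1.65). The separate values of all these genes are uncertain. SLC7A5 holds CCCGAGA in its 3' UTR.

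MYC targets and cytosolic ribosomal proteins fell. For the ribosomal proteins the camera p at the preset correlation of 0.01 overstates the evidence, since their estimated correlation was 0.669. Of 36 measured MYC targets, 25 fell and 3 rose over all genes tested, and 26 fell and 3 rose adjusted over the list alone, with a median log2 fold change of -0.22 (camera adjusted p = 3.7e-06; adjusted p = 0.44 with an estimated correlation). SLC7A5 fell by 1.68 on the log2 scale, SRM, the spermidine synthase, by 1.44, SLC3A2, the partner chain of SLC7A5, by 1.32 and the DNA repair enzyme APEX1 by 0.97. Of 45 cytosolic ribosomal proteins, 35 fell and none rose, both over all genes tested and adjusted over the list alone, with a median of -0.17 (camera adjusted p = 3.7e-06; adjusted p = 0.55 with an estimated correlation); RPL35 fell by 1.03 and RPL4 by 0.58. Of 28 ribosome biogenesis factors, 14 fell and 1 rose, the same counts adjusted over the list alone (median -0.13, camera adjusted p = 0.01; adjusted p = 0.44 with an estimated correlation), with DDX21 at -0.56 and WDR12, which also holds CCCGAGA, at -0.48. Among the 13 MYC family members and partners, MYC and ZBTB17 (-0.42) were among 4 that fell and MYCN (1.57) was the 1 that rose, with the same counts adjusted over the list alone; the list as a whole was not called (camera adjusted p = 0.4).

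Genes of the amino acid response fell. Of 24 measured members of the ATF4 list, 20 fell and 2 rose, the same counts adjusted over the list alone, with a median of -0.70 (camera adjusted p = 1.3e-06; adjusted p = 0.44 with an estimated correlation). Besides STC2 and SLC7A5 these included PSAT1, an enzyme of serine synthesis, at -0.97. SLC7A5, SLC3A2 and SHMT2 stand in both the MYC and the ATF4 list. The nucleotide synthesis list shares SHMT2 and MTHFD2 with the ATF4 list, and SHMT2 and IMPDH2 among others with the MYC list. Calls of these lists are therefore not independent. Nucleotide synthesis fell for 12 and rose for 2 of 23 members, the same counts adjusted over the list alone (median -0.13, camera adjusted p = 0.013; adjusted p = 0.44 with an estimated correlation), with MTHFD2 at -0.60 and PFAS at -0.54.

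Of 28 nuclear-encoded oxidative phosphorylation genes, 14 fell and none rose, the same counts adjusted over the list alone (median -0.13, camera adjusted p = 0.0067; adjusted p = 0.55 with an estimated correlation), with NDUFA10 at -0.45 and CYC1 at -0.43. Of 23 TCA cycle genes, 10 fell and 1 rose, the same counts adjusted over the list alone (median -0.12, camera adjusted p = 0.042; adjusted p = 0.47 with an estimated correlation); CS fell by 0.44, and IDH1, the cytosolic enzyme, was the 1 that rose, by 0.65. The TCA call was lost in 10 settings (camera adjusted p from 0.061 to 0.13), among them those without shcontrol replicate 2 (camera adjusted p = 0.084), shBDH1 replicate 1 (0.12) or shBDH1 replicate 2 (0.063); the oxidative phosphorylation call was lost without shBDH1 replicate 1 (0.056). The 13 mitochondrially encoded mRNAs had a median of -0.01, with 2 that rose and 3 that fell, the same counts adjusted over the list alone (camera adjusted p = 0.85), and their median changed sign with some scalings. They made up 3.72% to 3.86% of reads in each library. Of 11 ketone body and monocarboxylate transport genes, 2 rose and 4 fell, or 2 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.67); besides BDH1, the lactate and ketone carrier SLC16A1 (-0.27) fell and SLC16A7 (0.56) rose.

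Cell cycle genes were split. Of 31 genes of G2/M and mitosis, 18 fell and 3 rose, or 18 fell and 4 rose adjusted over the list alone (median -0.24, camera adjusted p = 0.0091; adjusted p = 0.44 with an estimated correlation); the mitotic transcription factor FOXM1 fell by 0.99 and KIF20A by 0.62. G1/S regulators went both ways, 10 up and 8 down of 23, the same counts adjusted over the list alone (camera adjusted p = 0.67), with MYBL2 at -1.34, CDK6 at 0.70 and RB1 at 0.74. Among 6 CDK inhibitors, CDKN1A (p21) rose by 2.53 and CDKN2D by 0.72 while CDKN2C and CDKN3 fell, the same counts adjusted over the list alone (camera adjusted p = 0.84); their median was -0.01, while their mean of 0.39 and the test pointed up. DNA replication genes had 5 that rose and 10 that fell of 31, the same counts adjusted over the list alone (camera adjusted p = 0.23). None of 12 measured replication-dependent histones passed the test, by limma over all genes or adjusted over the list alone (camera adjusted p = 0.54), and 0 did so at an unadjusted limma p or by edgeR.

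Activation genes rose. Of 23 T cell activation and immediate early genes, 18 rose and 1 fell, or 19 rose and 1 fell adjusted over the list alone, with a median of 1.09 (camera adjusted p = 1.3e-06; adjusted p = 0.44 with an estimated correlation). EGR1 rose from 2293 ± 148 to 6017 ± 419 normalized counts (SD, n = 2 each), CD69 by 1.66, IER3 by 1.72 and JUNB by 1.01 on the log2 scale. IER3 stands in the NF-kB list too. The 1 that fell was ATF3 (-1.05), a stress gene that the ATF4 list also holds and that is named here after its values were seen. NF-kB response genes had 6 that rose and 1 that fell of 13, the same counts adjusted over the list alone (median 0.16, camera adjusted p = 0.018; adjusted p = 0.44 with an estimated correlation), among them NFKB1 at 0.61; without shBDH1 replicate 2 the camera adjusted p was 0.06. Interferon response genes had 16 that rose and 1 that fell of 29, the same counts adjusted over the list alone (median 0.50, camera adjusted p = 0.00014; adjusted p = 0.44 with an estimated correlation), among them OAS2 at 1.02 and OAS3 at 0.67.

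HSPA5 (BiP), a chaperone of the endoplasmic reticulum, rose from 5796 ± 131 to 18728 ± 282 normalized counts (SD, n = 2 each), a log2 fold change of 1.69, and HSP90B1 rose by 0.85. Of 19 unfolded protein response genes, 13 rose and 5 fell, the same counts adjusted over the list alone (median 0.43, camera adjusted p = 0.0091; adjusted p = 0.44 with an estimated correlation); EDEM1, which directs misfolded proteins to degradation, fell by 0.74. Heat shock genes had 8 that rose and 3 that fell of 11, the same counts adjusted over the list alone, without a call for the list (camera adjusted p = 0.11); HSPA8 rose by 0.99 while the regulator HSF1 fell by 1.10. Of 21 pro-apoptotic genes, 12 rose and 3 fell, or 13 rose and 3 fell adjusted over the list alone (median 0.26, camera adjusted p = 0.033, or 0.44 with an estimated correlation), with CASP8 at 1.02 and FAS at 0.83. The call was lost in 3 settings, among them those without shcontrol replicate 2 or shBDH1 replicate 2. Of 8 anti-apoptotic genes, 4 rose and none fell, or 5 rose adjusted over the list alone (camera adjusted p = 0.089), with BCL2 at 0.82 and MCL1 at 0.59. Among 19 p53 targets, 8 rose and 3 fell, the same counts adjusted over the list alone (camera adjusted p = 0.11), although SESN2 fell by 1.42.

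T cell identity genes moved apart. Of 33, 16 rose and 11 fell, the same counts adjusted over the list alone (camera adjusted p = 0.41): CD7 rose by 1.27, while the recombinases RAG1 and RAG2 fell by 0.96 and 1.00 and the lymphoid factor IKZF1 by 0.80. Of 16 genes of the TAL1 complex and its targets, 8 rose and 6 fell, the same counts adjusted over the list alone (camera adjusted p = 0.65); ALDH1A2 fell by 0.70 and TCF12 by 0.74. NOTCH genes had 8 that rose and 1 that fell of 16, the same counts adjusted over the list alone (camera adjusted p = 0.058), with DTX1 at 1.65 and NOTCH1 at 0.43.

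Chromatin regulators and lipid genes showed no shared direction past the list test. Of 28 histone acyltransferases and deacylases with bromodomain readers, 6 rose and 11 fell, the same counts adjusted over the list alone (camera adjusted p = 0.18), with BRD3 at -1.04. Of 28 histone methyltransferases and demethylases, 6 rose and 13 fell, or 14 fell adjusted over the list alone (camera adjusted p = 0.2), with KDM2B at -0.78. Fatty acid oxidation had 5 that rose and 5 that fell of 18 (camera adjusted p = 0.87; median -0.02, mean 0.02), fatty acid synthesis 3 and 3 of 12 (camera adjusted p = 0.84; median -0.00, mean 0.09) and glycolysis 7 that rose and 5 that fell of 20 (camera adjusted p = 0.46), each with the same counts adjusted over the list alone. Cholesterol synthesis had 5 that rose and 6 that fell of 21, or 6 and 8 adjusted over the list alone (camera adjusted p = 0.81), with DHCR7 at -0.73. Hypoxia genes had 6 that rose and 4 that fell of 17, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.41), and autophagy and lysosome genes 8 and 3 of 19, the same adjusted over the list alone (camera adjusted p = 0.18).

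Some markers of other cell types rose. Genes of low count rose more often than they fell in general: of 5379 at a mean under 100, 635 rose and 188 fell. Genes at 0 numbered 1601 and 1644 in the shcontrol libraries and 970 and 1067 in the shBDH1 libraries. The marker lists were not tested against genes of like count. Of 7 NK and cytotoxic markers, 4 rose and none fell, the same counts adjusted over the list alone (median 1.09, camera adjusted p = 0.047; adjusted p = 0.44 with an estimated correlation): GZMA went from 79.9 ± 16.2 to 369 ± 29.2 and NKG7 from 15.9 ± 13.7 to 98.2 ± 27.9 normalized counts (SD, n = 2 each). The call of this list was lost in 11 settings (camera adjusted p from 0.051 to 0.083), among them edgeR on the recovered reads (0.051) and those without shcontrol replicate 2 (0.052) or shBDH1 replicate 2 (0.071). Of 5 B cell markers, 2 rose and none fell, the same counts adjusted over the list alone (camera adjusted p = 0.41), with CD79A going from 135 ± 13.3 to 601 ± 1.28. Myeloid markers had 1 that rose of 4 measured, erythroid and megakaryocyte markers none of 2, and fibroblast and epithelial markers 2 of 4; these lists were too small for a list test.

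**Figure D2:**
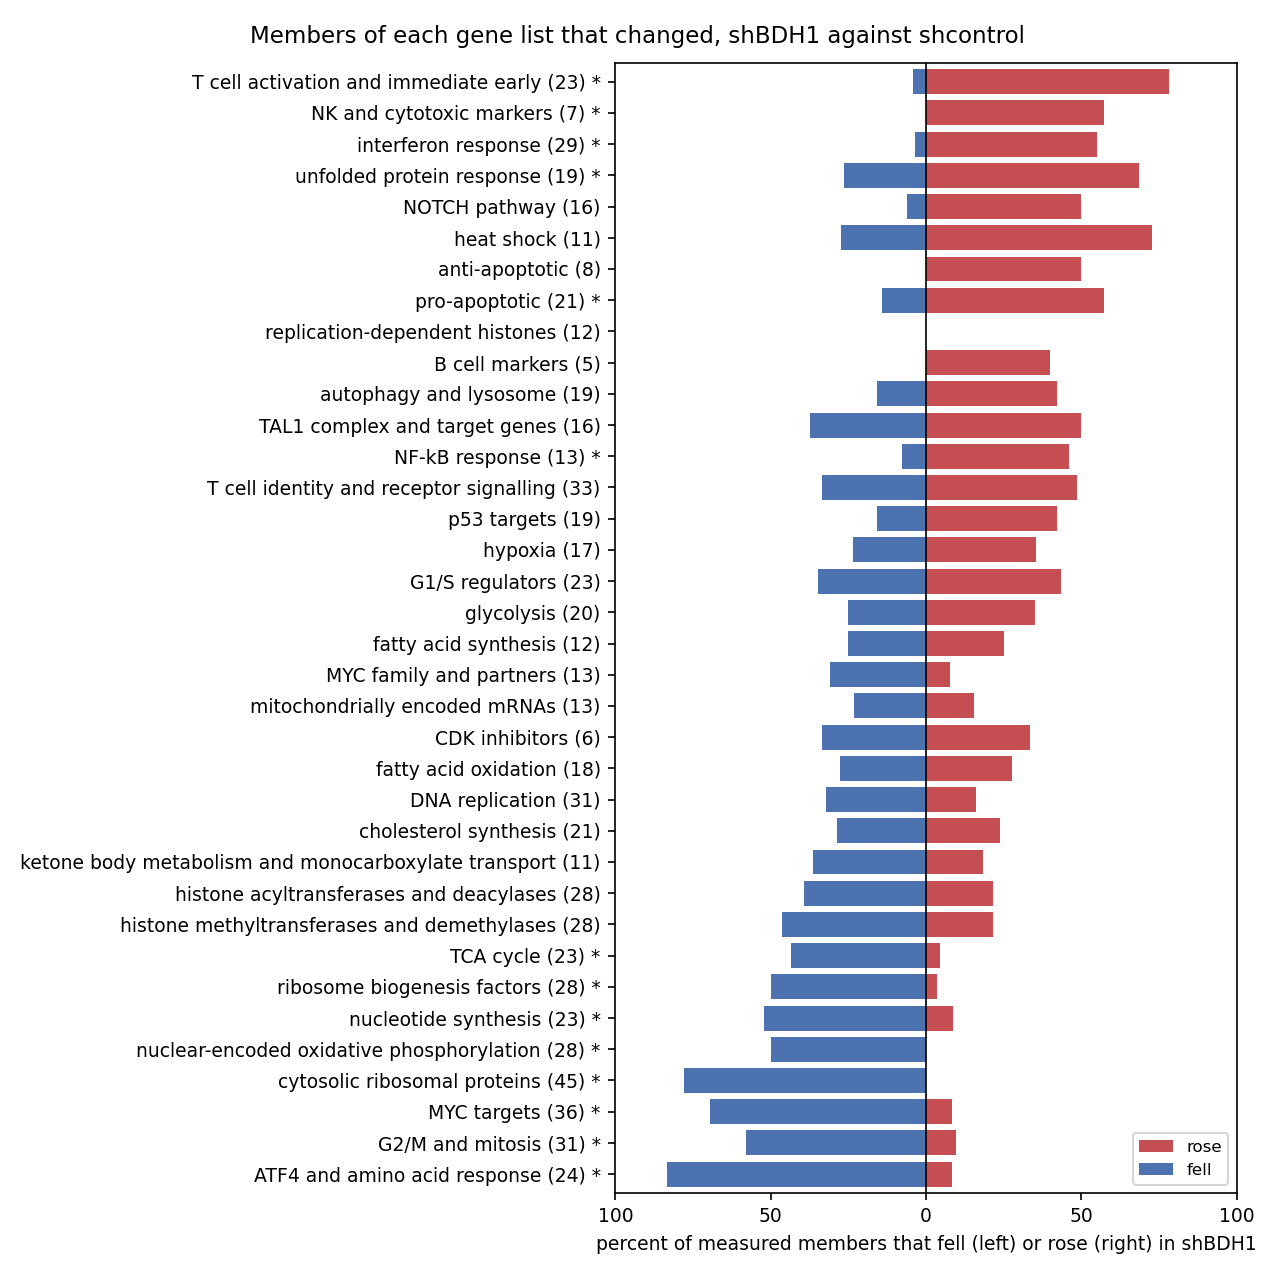
Percent of measured members that rose (right) or fell (left) in shBDH1 against shcontrol at a limma adjusted p under 0.05, for 36 gene lists ordered by median log2 fold change, with the number of measured members in parentheses and an asterisk where camera called the list at its preset correlation. The ATF4 list stands at the bottom with 20 of 24 members down and the activation list at the top with 18 of 23 up.

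Camera called 6 lists higher and 8 lower at its preset correlation, and none with an estimated correlation, where the smallest adjusted p was 0.44. The latter test had little power: in simulated reads, a list of 24 genes lowered 1.5-fold had a camera p of 2.5e-24 preset and 0.0078 estimated. The activation list had an estimated correlation of -0.044, below the preset one, yet its unadjusted camera p went from 7.4e-08 to 0.027. The lack of calls therefore does not decide against the lists. Low power was not the only difference, however. The estimated correlation was 0.669 for cytosolic ribosomal proteins and 0.240 for oxidative phosphorylation, against the preset 0.01. The preset camera p-values of both lists thus overstate the evidence. Without shBDH1 replicate 2, only 3 lists were called higher, since the pro-apoptotic, NF-kB and cytotoxic lists were no longer called.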

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

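The alternatives chosen after seeing the data were edgeR on the recovered reads with TMM factors, the limma pseudocounts, filters and rescalings, and leaving out genes with CCCGAGA in the 3' UTR. Of 160 genes named or listed for naming, 150 kept their direction and their side of the threshold in up to 22 settings, and none reversed (19 calls lost and 1 gained in single settings); BDH1 ranged from -0.57 to -0.36, MYC stayed at or below -0.95 and CDK4 ranged from -0.60 to -0.51. edgeR called 3968 genes higher and 3907 lower, 7720 of them shared with limma in the same direction, and DESeq2 called 3091 and 3105. Requiring an absolute log2 fold change of at least 1 left 909 higher and 312 lower, and edgeR's glmTreat against 1.5-fold called 711 and 303, as stricter criteria must give fewer. Upper-quartile factors gave 4447 higher and 3267 lower and library totals only 4215 and 3598, so the direction with more calls turned. The median of all genes moved most under upper-quartile factors, by 0.050. Leaving out CCCGAGA genes gave 3841 higher and 3871 lower.

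Camera with an estimated correlation called 0 lists higher and 0 lower, with 1 list at an unadjusted p under 0.05, and fry called 13 higher and 10 lower. edgeR at a mean CPM of at least 5 called 5 lists lower, losing the TCA cycle, nucleotide synthesis (adjusted p = 0.059) and ribosome biogenesis (0.054) lists. Without 1 library at a time, 3 to 6 lists were called higher and 6 to 8 lower, with the lone library of a group assumed to vary like the other group. At the preset correlation the TCA cycle list missed the threshold in 10 settings (adjusted p from 0.061 to 0.13) and the cytotoxic list in 11 (0.051 to 0.083). Without shcontrol replicate 2 the pro-apoptotic list had an adjusted p of 0.084, and without shBDH1 replicate 1 the oxidative phosphorylation list had 0.056. The direction of camera's test turned for 4 lists, none of them called. For mitochondrially encoded mRNAs the median then was 0.03, against -0.01, with upper-quartile factors, 0.01 with library totals only or equal totals, 0.02 at a mean CPM of at least 5, and from -0.06 to 0.01 with 1 library left out. For fatty acid oxidation the test turned with no filter in edgeR and in limma while the median stayed at -0.02, and the median went from -0.03 to 0.02 with 1 library left out. At a mean CPM of at least 5 the test turned for TAL1 genes, with a median of -0.02 against 0.18, and for cholesterol synthesis, whose median kept its sign at -0.05 and ranged from -0.08 to 0.02 with 1 library left out. Over all lists and settings 43 calls were lost, 11 gained and 685 results stayed; lists were not run with edgeR robust, DESeq2 or limma-voom. The cause of these changes was not tested.

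The replicate numbers were not taken to pair the libraries, as no label ties them; the deviations of same-numbered libraries from their group means correlated across genes at 0.001, and at 0.051 over 9823 genes with a mean of at least 500. With the number as a block, limma called 4108 genes higher and 4217 lower and edgeR 4153 and 4144; 5 lists were called higher and 7 lower by camera on the blocked limma fit, and 4 and 7 on the blocked edgeR fit. At low depth precision was poorer, with a median SE of 0.50 at a mean under 100 against 0.064 at 1000 or more.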

Other observations

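The gene families and all tests in this part were chosen after the fold changes were seen, apart from the scan for the seed of the hairpin. The camera p-values of the families therefore overstate the evidence. Some families also hold genes already counted above. MRPL37, ETV5 and KRT72 are among the largest changes, and JUNB, FOS and DUSP6 stand in the activation list. Over 18 families, tested once with camera and adjusted over the 18, mitochondrial ribosomal proteins fell in 43 of 69 members and rose in none, with a median of -0.24 (camera adjusted p = 1.4e-07); MRPS2 fell by 0.64. Cytosolic tRNA synthetases, which load amino acids onto tRNAs, fell in 13 of 17 members and rose in 1 (camera adjusted p = 0.00055), with CARS at -0.89 and GARS at -0.84. RNA polymerase subunits fell in 19 of 28 and rose in 1 (camera adjusted p = 0.00051) and eukaryotic initiation factors fell in 23 of 52 and rose in 5 (camera adjusted p = 0.022). Families called lower or higher kept direction and call in 6 of 6 scalings. This says little, since camera compares a family with all other genes, and a scaling that shifts all genes alike hardly moves it. With an estimated correlation camera called none of the 18, the smallest adjusted p being 0.24.

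Several surface and signalling families rose. Some of their members were of low count, where rises outnumbered falls in general, such as CCR1 (mean 0.511 in shcontrol and 39.7 in shBDH1). Chemokine receptors rose in 9 of 14 members and fell in 2, with a median of 1.82 (camera adjusted p = 0.0018); CCR7, which guides T cells to lymph nodes, rose by 2.52 and CCR4 by 1.61. Feedback genes of ERK signalling (Sprouty, SPRED, ETV and DUSP genes) rose in 10 of 14 and fell in none (camera adjusted p = 0.00014), with SPRY4 at 2.30 and DUSP6 at 1.78. Integrins rose in 12 of 22 and fell in 2 (camera adjusted p = 0.0019), with ITGA4 at 0.86. RAB GTPases rose in 23 of 47 and fell in 7 (camera adjusted p = 0.001), guanine nucleotide exchange factors rose in 11 of 20 and fell in 3 (camera adjusted p = 0.0065), and MHC class I genes rose in 5 of 8 and fell in 1 (camera adjusted p = 0.038). AP-1 genes rose in 6 of 9 (camera adjusted p = 0.001) and keratins in 4 of 8 (camera adjusted p = 0.013), and none of either fell. The estimated-correlation test called none of these (smallest adjusted p = 0.24). Proteasome subunits (11 rose, 9 fell of 35), ZNF genes (39 and 83 of 377), MHC class II (0 and 1 of 11), chaperonin subunits (0 and 6 of 8), SLC25 carriers (6 and 15 of 41) and microRNA machinery (6 and 3 of 12) were not called.

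BDH1 mRNA fell by less than 1515 other genes. Off-target silencing by the hairpin's seed may account for part of this. The scan covered 11028 genes with a mean of at least 100 and a usable annotated 3' UTR. Of all heptamers, CCCGAGA in 3' UTRs had the lowest t (-6.63, Bonferroni bound -4.67) after adjusting for GC content, 3' UTR length and expression. BDH1 holds CCCGAGA in its last exon (exon 8 of 8, 3' UTR, chromosome 3 from 197511389 to 197511395, hg38). Among the genes scanned, 16 of the 100 most lowered carried CCCGAGA against 2 of the 100 most raised. The median log2 fold change was -0.13 with CCCGAGA, -0.28 with GCCCGAGA and -0.22 with CCCGAGAA. These counts and medians come from the same fold changes that picked CCCGAGA, so they are not separate support. The scan does not decide for a seed, because 23 heptamers lay below the bound, and some, such as GTGAGCC (2007 genes, t = -5.37), do not overlap CCCGAGA. Several overlap one another, as AGGCGTG, GGCGTGA and GTGAGCC do, so the 23 are not separate signals. The 1-base shifts of CCCGAGA, GCCCGAG and CCGAGAA, had adjusted log2 differences of -0.137 and -0.147, but the unrelated CGCAACC had -0.150. Of the 23, 18 occur in the 17 annotated BDH1 transcripts, where 37.6% of all heptamers do. The hairpin's sequence is not given in the sources used here. When the lowest heptamer was picked on 1 set of chromosomes and tested on the others, even chromosomes gave GTGAGCC (held-out t = -2.70) and odd ones GCCCGAG (held-out t = -1.74). GCCCGAG is CCCGAGA moved by 1 base, but its held-out difference was only -0.069 (SE 0.040). Neither a seed nor GC content and length is therefore singled out. Among the 11028 genes scanned, CCCGAGA stands in 2.9% of all, 4.4% of those that fell and 14.6% of those called at least 2-fold lower (20 of 137). The 312 genes called at least 2-fold lower over all genes tested include genes outside the scan. Most of the change, MYC and CDK4 included, therefore stays open, with the lowering of BDH1 itself as an untested biological explanation.

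Genes with 3' UTR sites of T-cell microRNAs lay higher in shBDH1: 12 families had a median t of 2.55 (10 above 0) against -0.28 (3 above 0) for 9 families of other tissues (one-sided exact permutation p = 0.0036). The family list was written after the highest heptamers had been seen, among them TTTGCAC of miR-19 (t = 5.63), so this p overstates the evidence. The shifts were small: the largest adjusted log2 difference of the 12 families was 0.077, for miR-142-3p. Those below 0 were let-7 (t = -0.89) and miR-150 (t = -1.65). Lower output of the MYC-driven miR-17-92 cluster alone was argued against only weakly. The 9 families outside it also lay above the other tissues (one-sided exact permutation p = 0.028). This p comes from the same list and overstates the evidence too, as ACACTAC of miR-142-3p (t = 4.42) was also among the highest heptamers. The cluster's host transcript MIR17HG was not lower (0.32, SE 0.16, limma adjusted p = 0.12), but it does not measure the mature microRNAs. Both groups carried a hairpin, so competition for Argonaute could account for the pattern only if the hairpins differed in amount or processing. Neither was measured here. A change in the cells' own microRNA machinery stays open beside it: DROSHA fell by 1.07 and AGO2 by 0.34 on the log2 scale, while DICER1 rose by 0.78 and TNRC6A by 1.43.

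Libraries of 1 group differed by more than random draws of reads, with a variance over Poisson at 5 to 20 reads per pair of 3.30 in shcontrol and 3.21 in shBDH1. Counting both mates of a fragment gives at most 2 and is argued against as the whole cause, since the lowest ratio of any range from 20 to 1000 reads per pair was 3.29. Even counts from 2 to 10 were nevertheless 1.10 to 1.16 times as frequent as their neighbours. Differences between cultures stay open: the ratio of 3.21 rests on genes of few reads, whose spread between cultures is not known, and above 5000 reads per pair the ratio was 10.5 in shBDH1 and 4.56 in shcontrol. No biological explanation was tested.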
